A study of Drosophila melanogaster with 3 samples.

How the data were processed

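Anti-GFP chromatin immunoprecipitation libraries of whole prepupae were made by the authors from a line with C-terminally GFP-tagged CG9139 (Rabex-5), with 3 biological replicates in 1 group. Per the deposited text notes, reads of each replicate and of the 3 replicates pooled were compared with 1 control alignment shared by the replicates, on dm6 and on dm3, to give relaxed lists of 30000 candidate regions, and the candidate lists were thresholded by the irreproducible discovery rate (IDR). The aligner, the peak caller and the IDR threshold are not given in the sources used here. What the control alignment was made from is not given there either, and a library without the tagged protein was not analysed here. The signal in each deposited list is the authors' enrichment value relative to the control alignment. It scales with depth, so it was used as a rank or as a ratio to a median within a list. The deposited lists also hold -log10 q values by the authors' caller, which reach their maximum at 74.8% of the dm6 IDR peaks and were therefore not used to rank. No list holds read counts, so depth per sample is unknown, and exact intervals cover counting error only. On both builds the IDR list was exactly the top of the pooled list by signal, with 4934 regions on dm6 and 4309 on dm3.

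Regions were read with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plotted with matplotlib 3.10.9. Genes and sequence came from Ensembl release 115 annotation and the soft-masked Release 6 genome. Analyses used the 7 major arms, on which all dm6 regions lay. The strongest candidates of a replicate were as many as there were IDR peaks, by signal, and regions were shared if they overlapped by at least 1 bp, tested against 1000 random relocations within arms. A summit within 500 bp of a protein-coding TSS was called TSS-proximal, and classes were compared with 10000 relocations of the summits on the same arm, avoiding unknown bases. Arms were compared with their share of known bases by exact binomial tests. A gene was bound if a summit lay within 500 bp of any of its TSSs. Gene lists and biotypes were compared with all other protein-coding genes, or with all protein-coding genes, by two-sided Fisher's exact tests. The 32 lists held 558 matched symbols of 568 named and families found by symbol. Motifs were sought on both strands within 100 bp of the summit, in windows of 201 bp, and compared with a window 1000 bp to one side by exact McNemar tests, as were all words of 6 bases. The trend with signal was tested by 100000 permutations across peaks. Each family of tests was adjusted by Benjamini and Hochberg's method at a false discovery rate of 5%.

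The lists, motifs, tests, main alternatives and the rule for naming genes were fixed before the data were examined. Named were the tagged gene, the genes nearest to the 25 peaks of highest signal that recurred among the strongest candidates of all 3 replicates (by position and host gene where the TSS was over 1 kb away), up to 4 bound members of each list by signal, and at most 5 genes with 3 or more summits near their TSSs. The members of a few other sets named in the text were chosen after their values were seen: the peaks of chromosome 4, genes with many summits, families grouped by symbol and genes with the word CACTGAGA. Alternatives fixed beforehand were promoter distances of 200 and 1000 bp, TSSs of all genes, the peaks above the median signal, pooled candidates outside the IDR peaks as background, clusters of list members within 5 kb counted once, windows of 50 bp to each side, flanks at 2000 bp, TSS-proximal or distal peaks alone, other overlap rules and list lengths, the dm3 lists, and leaving out each replicate in turn. Chosen after seeing the data were 10000 random gene sets matched on 4 classes of TSS number and 5 of gene length, shuffled summit windows that keep dinucleotide counts, the unmasked length and the pooled candidates as background for arms, the alternatives for biotypes, and leaving out replicates for motifs, arms and the number of peaks. Leaving out a replicate kept the IDR peaks, called from all 3 replicates, that lay among the strongest candidates of both others. For the overlap between replicates it left the pair of the others. A cluster of list members counted as bound if any member was, and was compared with single other genes.

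The procedures were tested on simulated data made from the same genome. A planted promoter excess was called in 10 of 10 runs, and none was called in 10 runs without one. Planted gene lists were called 100 of 100 times, another list was called in 1 of 50 such runs, and no list was called in 50 runs with none planted. Apart from planted lists, each gene was bound independently with the same probability, so these runs do not cover gene clusters or shared peaks. When only the TSS number set the binding, 0 of 640 lists were called with matching and 1 of 640 without it, so this run does not show whether matching removes false calls. A planted motif was called in 3 of 3 runs, and 0 of 93 motifs and 0 of 6240 words were called where none was planted. Summits in these runs lay at random positions. They therefore do not show how many calls arise from differences in location or GC content between real summits and flanks. With 61.1% of regions kept in place, 62.2% were found shared. With summits spread by length, an arm was called in 4 of 100 runs. A planted trend with signal was called in 5 of 5 runs, and none in 5 runs without one.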

Results

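Chromatin immunoprecipitation with sequencing was performed on whole prepupae of both sexes, labelled 24 hours, from a transgenic fly line that expresses CG9139 with green fluorescent protein (GFP) fused to its C-terminus. CG9139 is Rabex-5, an exchange factor for the endosomal GTPase Rab5 that also carries a ubiquitin ligase domain. Chromatin was sheared to 200 to 800 bp and precipitated with an antibody against GFP in 3 biological replicates, which formed the only group, so no comparison between groups was possible. The question addressed was where in the genome the tagged protein is recovered. The files were ranked lists of regions without read counts, so the sequencing depth behind each value is unknown. On the dm6 (Release 6) build, 30000 candidate regions were listed for each replicate and for the pooled reads. The list thresholded by the irreproducible discovery rate (IDR) held 4934 peaks with a median width of 430 bp. Merging overlapping regions left 4629. The signal of a peak is the authors' own value, and it was used only to rank or describe peaks within a list. Where a relative signal is given, it is a replicate's signal divided by that replicate's median over the IDR peaks, averaged over the replicates that listed the region. Genes and peaks are not replicates, and the p-values below hold for these 3 replicates only.

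Nearly all IDR peaks overlapped a candidate region in every replicate, the weaker peaks included. The IDR peaks were the top of the list from the pooled reads of these same replicates, so this recovery is in part built in. No random level was computed for the overlap of IDR peaks with candidates. Among each replicate's 4934 strongest candidates, 69.9% overlapped one of another replicate's strongest candidates (mean of the 6 ordered pairs of 3 replicates), with pairs between 67.0% and 71.5%. The SD of 1.85 is over these pairs, which are not independent. Random relocation within chromosome arms gave 2.67% to 2.79% (p = 0.002, the smallest that 1000 relocations can give, permutation test). IDR peaks were found among the strongest candidates of replicates 1, 2 and 3 at 82.6%, 79.6% and 79.7%. A total of 2862 IDR peaks (58.0%) lay among the strongest candidates of all 3 replicates, and 4777 (96.8%) overlapped some candidate in all 3. Peaks found among the strongest candidates of the other replicates numbered 3269 when replicate 2 was left out, and 3320 and 3323 without replicates 1 and 3. Overlap with some candidate in all 3 was 98.8% for the 494 peaks with the highest signal and 94.5% for the 493 with the lowest. Presence among the strongest candidates of all 3 went from 98.8% to 8.32% over the same bins, a fall that is in large part set by using lists as long as the IDR list, at whose end the weakest peaks lie. Across the peaks listed in both members of a pair, the Spearman correlation of signal was 0.667, 0.603 and 0.708. These correlations run across peaks, which are not independent.

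**Figure D1:**
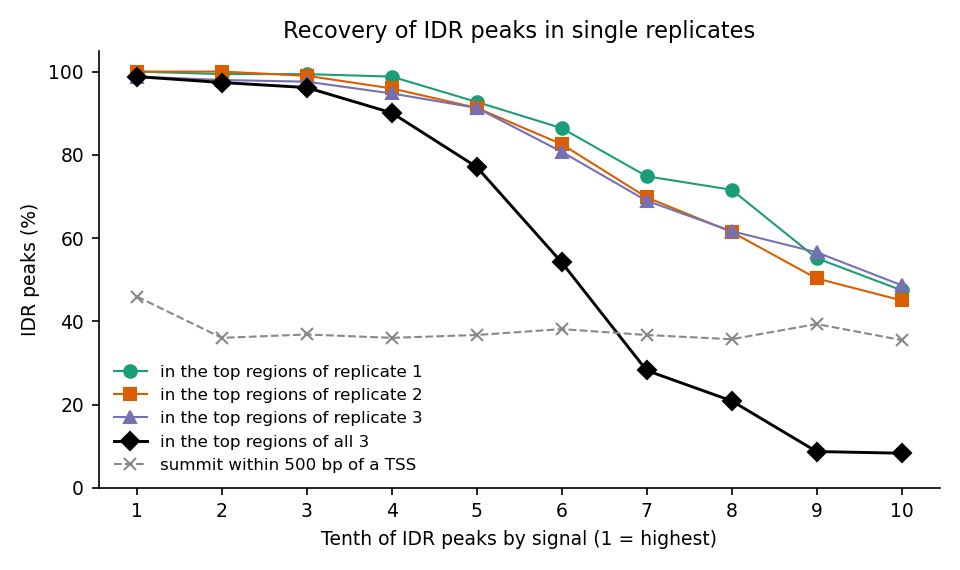
Recovery of IDR peaks in single replicates. The x axis gives the peaks in 10 bins of signal, 1 being the highest, and the y axis the percent of each bin found among the strongest candidates of replicates 1, 2 and 3 (coloured lines) or of all 3 (black line), with the percent of summits within 500 bp of a transcription start site as a dashed line. The black line goes from 98.8% to 8.32%, in large part because the lists compared are as long as the IDR list, while overlap with any candidate in all 3, not drawn, is 98.8% and 94.5% in the same bins.

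Promoters and introns of protein-coding genes held more peaks than random positions did, and coding exons held far fewer. Within 500 bp of a transcription start site (TSS) lay 1860 summits, or 37.7%, against 11.5% of random positions on the same arms, a ratio of 3.29. The strongest candidates of the single replicates gave 39.4% ± 1.70 (SD, n = 3). Introns held 54.9% of the summits against 42.1% of random positions, and 5′ UTRs held 12.2% against 3.06%. Coding exons held 1.03% against 17%, and 3′ UTRs held 1.03% against 4.94%. Intergenic sequence held 30.8% against 32.9% (permutation p = 0.0018). Each of the other differences had p = 0.0002, the smallest that 10000 relocations can give in this two-sided permutation test. Of the TSS-proximal summits, 66.6% lay upstream, with a median position of -69 bp, and 3074 summits (62.3%) lay farther than 500 bp from any protein-coding TSS. Most contrasts were smaller against the 23768 pooled candidates outside the IDR peaks, of which 15.9% were TSS-proximal (ratio 2.37), 51.8% lay in introns (1.06) and 6.13% in 5′ UTRs (1.99). Coding exons held 3.96% of them (0.261), 3′ UTRs 2.13% (0.485) and intergenic sequence 36.0% (0.857). Against random positions, the promoter ratio was 4.97 within 200 bp.

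**Figure D2:**
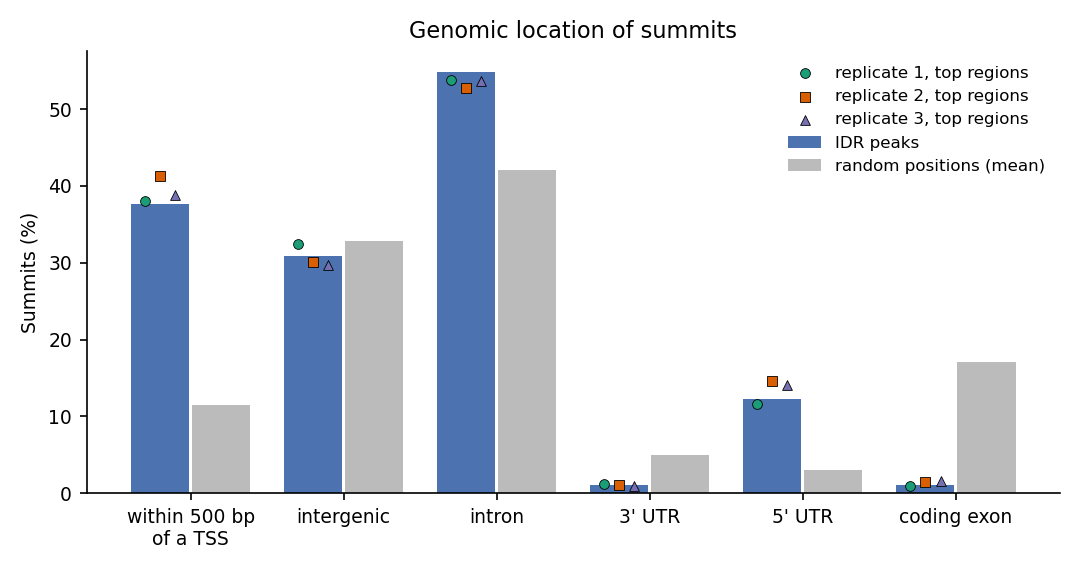
Genomic location of summits. Blue bars give the percent of IDR peak summits in each class on the y axis, grey bars the mean of random positions on the same arms, and markers the strongest candidates of each replicate. The share within 500 bp of a TSS is 37.7% for the IDR peaks and 11.5% for random positions.

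The peaks with the highest signal lay in introns, at promoters and between genes. Of the 25 strongest that recurred in all 3 replicates, 12 lay within 500 bp of a TSS and 10 lay beyond 1 kb. The highest signal, 3054, belonged to a peak at chromosome arm 2R 22569706 to 22570507 in an intron of dnr1, a negative regulator of the Imd immune pathway, and its relative signal was 16.6 ± 1.41 (SD, n = 3). The next peak lay in an intron of Cat, which encodes catalase, at 3L 18822624 to 18823191, with its summit 319 bp downstream of the TSS and a relative signal of 13.4 ± 1.13 (SD, n = 3). An intergenic peak at 3L 3246214 to 3246867 had 12.1 ± 1.05. A peak 28 bp upstream of Ugalt, a nucleotide sugar transporter gene, had 11.6 ± 1.98 (X 2703696 to 2704068). Peaks at yip2, in an intron at 2L 9915144 to 9915697, and at larp, which encodes an RNA-binding protein, at 3R 28326319 to 28326824, had 11.7 ± 1.09 and 9.97 ± 1.52. CG32772 on the X chromosome held a pair of these peaks, at 4910035 to 4910813 in an intron and at 4908910 to 4909431 in its 5′ UTR. A peak at X 15069269 to 15070139 lay in the 3′ UTR of Lsd-2, a lipid droplet protein gene. The TSS nearest to a further pair, at 480894 to 481285 and 478940 to 479356 on 2L, was that of cbt, although both also lay within the gene ush. The others with a TSS within 1 kb were at CG14100, CG8788, puc, CG18549, CG13204, PNPase, CG43658, Lk6 and CenG1A. The rest of those beyond 1 kb lay in introns of CG11050 and brat or between genes, nearest to CG4004, CG31668 and scyl.

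A summit lay within 500 bp of a TSS of 1834 of 13968 protein-coding genes (13.1%; 14% ± 0.820 in the single replicates, SD, n = 3), called bound below. Among 32 gene lists, cytosolic ribosomal protein genes were bound most often by the IDR peaks, at 57 of 92. Their odds ratio against all other genes was 11.1 (adjusted p = 2.22e-26, two-sided Fisher's exact test, as for the other lists). Examples were RpS27 (FBgn0039300), with a peak at 3R 25247354 to 25247643 and a relative signal of 2.56 ± 1.71 (SD, n = 3), RpS4 with 2.62 ± 0.715 (n = 3), RpL7 with 2.42 ± 1.59 (n = 2) and RpS10b with 2.08 ± 0.811 (n = 3). This share varied more between replicates than those of the other lists did, at 77.2%, 64.1% and 39.1%. In replicate 3 it lay below the share of other lists, such as the 48.3% of ecdysone response genes. The odds ratio was 5.85 when replicate 1 was left out and 6.47 without replicate 2, both past the threshold. Both were below the 6.30 and 6.64 of the ecdysone response genes. Without replicate 3 the ribosomal ratio was the higher, at 10.8 against 8.18.

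Genes of the ecdysone response, the hormone response that drives metamorphosis, were bound at 16 of 29, with an odds ratio of 8.21 (adjusted p = 9.79e-07; 51.7% ± 3.45 in the single replicates, SD, n = 3, Fisher's exact test). They included Sox14 (FBgn0005612), a transcription factor gene induced by ecdysone, with a peak at 2R 23978391 to 23978709 and a relative signal of 4.26 ± 0.995 (SD, n = 3). Eip93F had 3.75 ± 0.562, the ABC transporter gene E23 had 2.69 ± 0.657, and the nuclear receptor gene Eip75B had 2.49 ± 0.497 (n = 3 each). Genes of chromatin regulators and insulator proteins were bound at 16 of 37, with an odds ratio of 5.08 (adjusted p = 3.95e-05; 39.6% ± 8.69, SD, n = 3, Fisher's exact test). Examples were the Polycomb group gene ph-p with 4.57 ± 1.99 (n = 3), psq with 3.53 ± 0.531 (n = 3), and E(z), the histone H3 lysine methyltransferase gene, with 2.09 ± 0.622 (n = 2). A peak near brm, a chromatin remodelling ATPase gene, had 3.02 ± 1.62 (n = 3) but lay closer to the TSS of Arl1. Notch pathway genes were bound at 13 of 32, with an odds ratio of 4.55 (adjusted p = 0.000538; 37.5% ± 3.13, SD, n = 3, Fisher's exact test). Examples were the target genes E(spl)mdelta-HLH with 2.65 ± 0.158 and E(spl)m7-HLH with 1.85 ± 0.0745, the Notch inhibitor numb with 2.06 ± 0.203, and aph-1, a subunit of gamma-secretase, with 1.79 ± 0.299 (n = 3 each). The summits of E(spl)mdelta-HLH and aph-1 lay closer to the TSSs of CG43116 and Snx21. In a permutation test against random genes matched on TSS number and gene length, a comparison chosen after seeing the data, these lists and the ribosomal proteins stayed past the threshold. The matched odds ratio was 2.65 for ecdysone genes (adjusted permutation p = 0.0411), well below the unmatched 8.21, and 3.43 for chromatin genes, 4.64 for Notch genes and 11.4 for ribosomal proteins (adjusted permutation p = 0.00427 each). The ecdysone value was lower than the 2.93 of the heat shock list, which lost the call. For the ecdysone genes the odds ratio was 5.12 with a distance of 200 bp and 4.74 in the peaks above the median signal. For chromatin genes it was 3.30 without replicate 1. For Notch genes it was 7.98 with clusters counted once, where a cluster was bound if any member was. That rule can itself raise the ratio. The Notch call ended at 200 bp (odds ratio 2.71, exact adjusted p = 0.0762).

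Another 4 lists passed the threshold against all other genes but lost the call against genes matched on TSS number and length. Glycolysis genes were bound at 7 of 15, with an odds ratio of 5.81 (exact adjusted p = 0.00653) that became 2.43 when matched (adjusted p = 0.316). Gapdh2, which encodes glyceraldehyde-3-phosphate dehydrogenase, had a peak at X 15867803 to 15868169 with a relative signal of 6.18 ± 0.768 (SD, n = 3), the enolase gene Eno 4.41 ± 0.879, the hexokinase gene Hex-A 2.97 ± 0.973 and the lactate dehydrogenase gene Ldh 1.5 ± 0.144 (n = 3 each). Heat shock and chaperone genes were bound at 10 of 28, with an odds ratio of 3.69 (exact adjusted p = 0.00658) that became 2.93 when matched (adjusted p = 0.0568) and 2.95 without replicate 2 (adjusted p = 0.0678). Examples were Hsp27 with 5.06 ± 0.428, Hsp83 with 4.64 ± 1.12, Hsc70-5 with 1.28 ± 0.682 and Hsp23 with 1.16 ± 0.161 (SD, n = 3 each). Genes of JAK-STAT and immune signalling also stood at 10 of 28, and the list lost its call in 4 of 8 alternatives, with an odds ratio of 1.63 when matched (adjusted permutation p = 0.532). The odds ratio was 2.95 without replicate 2 (exact adjusted p = 0.0678), 2.64 at 200 bp (adjusted p = 0.104) and 2.70 in the peaks above the median signal (adjusted p = 0.157). In this list the JNK phosphatase gene puc had 7.98 ± 0.986, the NF-kappaB factor gene Dif 1.69 ± 0.521 and Stat92E 1.17 ± 0.425 (SD, n = 3 each). A peak within 500 bp of imd, at 2.82 ± 0.0186, lay closer to Dp1. Genes of EGFR and Ras signalling were bound at 9 of 27, with an odds ratio of 3.32 (exact adjusted p = 0.0168) that became 1.93 when matched (adjusted p = 0.337) and 2.77 at 200 bp (adjusted p = 0.0955), and it was 5.02 without replicate 3. The phosphatase gene csw had 3.47 ± 0.643, edl 2.28 ± 0.725, the ligand gene spi 1.75 ± 0.332 and the ETS factor gene pnt 1.32 ± 0.329 (SD, n = 3 each).

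Structural genes of the cuticle were not bound, at 0 of 124 (exact adjusted p = 8.11e-07), which allows a share of up to 2.93% (exact 95% interval). Within 1000 bp their odds ratio was 0.0853, still past the threshold. Genes of oxidative phosphorylation were bound at 2 of 90, namely ND-ASHI and ATPsynC, with an odds ratio of 0.149 (exact adjusted p = 0.00348), but the call ended in the peaks above the median signal (odds ratio 0.280, adjusted p = 0.177). It was 0.373 within 1000 bp and 0.226 without replicate 3, both past the threshold. Among the histone genes 1 was bound, His3.3B, or 0.870% of the list, with an odds ratio of 0.0575 (exact adjusted p = 2.03e-05). That call rested on the repeated histone cluster, since counting clusters once gave an odds ratio of 1.31 (exact adjusted p = 0.680), and against matched genes it was 0.240 (adjusted permutation p = 0.337). Leaving out a replicate gave 0.0868 to 0.0938, and reads from multicopy genes cannot be placed with certainty. No other list passed the threshold in either direction. Wnt genes stood at 7 of 23, an odds ratio of 2.90 (exact adjusted p = 0.0644), including sgg, fz2, nkd and dally. This list passed the threshold in 4 of 8 alternatives, with an odds ratio of 4.24 within 200 bp (exact adjusted p = 0.0160), 2.81 within 1000 bp (0.0499), 3.62 without replicate 1 (0.0354) and 3.82 without replicate 2 (0.0339), but not against matched genes, where it was 1.32. Within 1000 bp the Hippo list was higher and the male germline list lower past the threshold (exact adjusted p = 0.0385 each), and without replicate 1 the proteasome list was lower, with no member bound (0.0490). Imaginal disc patterning genes stood at 10 of 43 (exact adjusted p = 0.140), including ct, Dll, ptc and salr. Mitochondrial ribosomal protein genes stood at 9 of 73 (exact adjusted p = 1), proteasome genes at 2 of 48, cell cycle and replication genes at 6 of 33, bHLH and proneural factors at 6 of 31, muscle genes at 6 of 28 and autophagy genes at 3 of 23. Hippo pathway genes stood at 4 of 14, apoptosis genes at 4 of 15, circadian clock genes at 3 of 10, glial genes at 3 of 12, genes of dosage compensation and sex determination at 2 of 11 and hemocyte genes at 1 of 18. Neuronal genes stood at 2 of 24 (exact adjusted p = 0.812), and against matched genes this list became lower, with 8.47 expected (adjusted p = 0.0230). None was bound of 26 male germline, 24 glue and larval serum protein, 18 antimicrobial peptide, 13 ecdysteroid synthesis and 11 Hox genes, where the short lists allowed upper limits of 13.2% to 28.5%. Leaving out single replicates moved several lists that were not called, such as muscle genes from an odds ratio of 1.81 to 0.399 without replicate 2, and cell cycle genes from 1.47 to 0.319 without replicate 1. Against matched genes several of these also changed direction, with mitochondrial ribosomal protein genes going from 0.930 to 2.48 (adjusted permutation p = 0.102), imaginal disc patterning genes from 2.01 to 0.826, circadian clock genes from 2.84 to 0.931 and muscle genes from 1.81 to 0.624, none past the threshold.

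**Figure D3:**
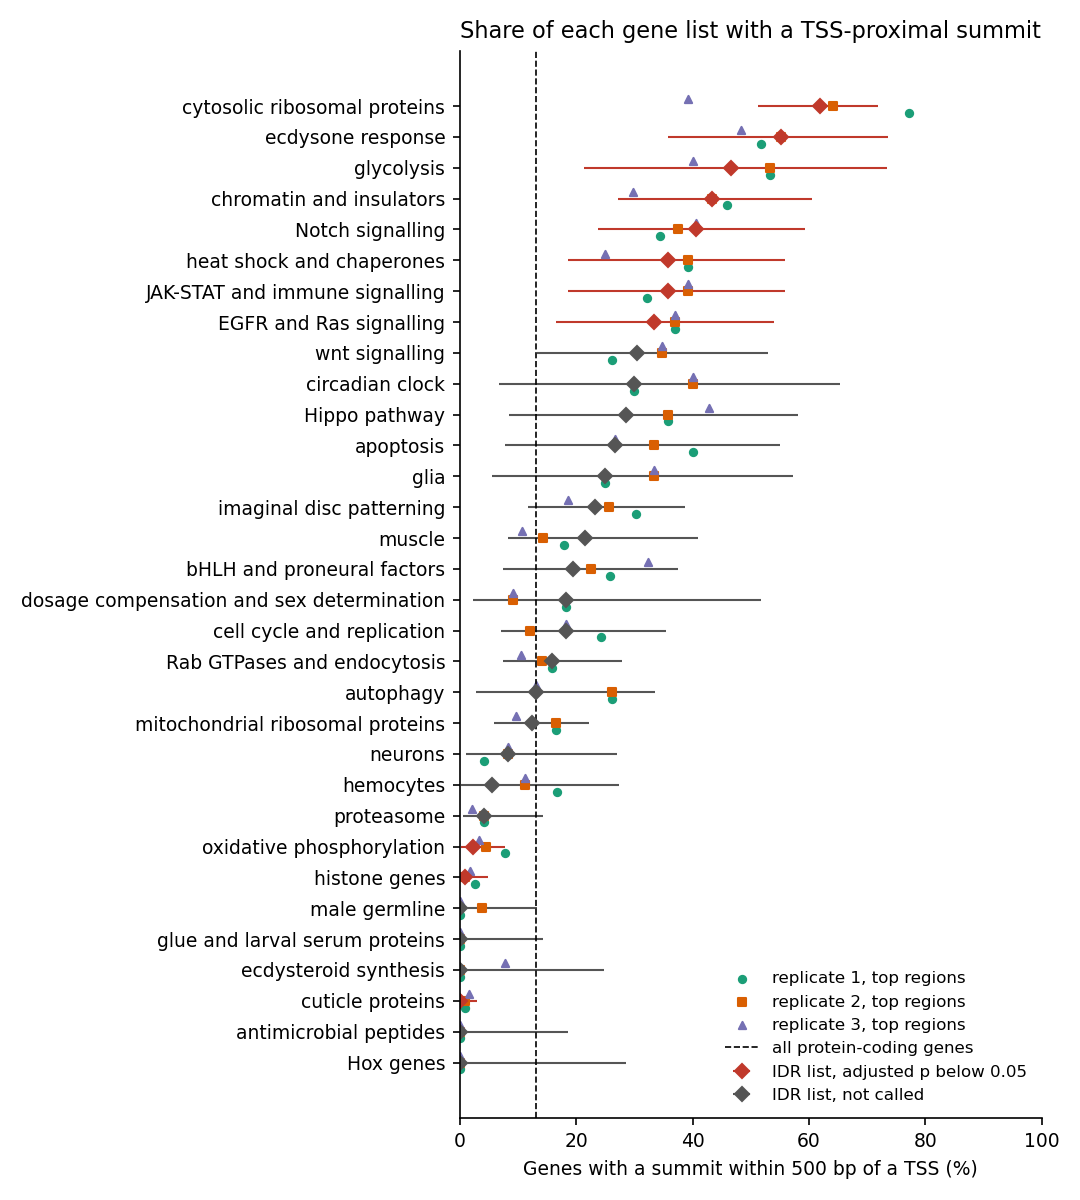
Share of each gene list with a TSS-proximal summit. The x axis gives the percent of a list's genes with a summit within 500 bp of a TSS, diamonds the IDR peaks with exact 95% intervals (red where the adjusted p passed the threshold), small markers the strongest candidates of each replicate, and the dashed line all protein-coding genes. Cytosolic ribosomal proteins lie at 62.0% and all genes at 13.1%.

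The gene of the tagged protein itself carried no IDR peak. Rabex-5 (FBgn0262937) lies at 3L 1295913 to 1298497, and the nearest IDR summit was 20794 bp away. No pooled candidate overlapped the gene either, and 1 candidate did in replicate 2, where it ranked 7782 of 30000. Genes of Rab GTPases and endocytosis were bound at 9 of 57, with an odds ratio of 1.24 (exact adjusted p = 0.633). The ratio was 0.771 without replicate 1, 0.753 without replicate 3 and 0.449 in the peaks above the median signal, none past the threshold, so this list had no stable direction. Rab5, the substrate of Rabex-5, had 3 summits near its TSSs, the strongest at 2L 2363624 to 2363913 with a relative signal of 3.67 ± 0.586 (SD, n = 3). Rab7 had 1.05 ± 0.125, Rab8 0.800 ± 0.418 and AP-2alpha, whose summit lay closer to the TSS of ebi, 0.760 ± 0.198 (n = 3 each). In all, 58 genes had 3 or more summits near their TSSs. The most were 6 at dnc, which encodes a cAMP phosphodiesterase, 5 at Svil and at SNF4Agamma, a subunit of AMP-activated kinase, and 4 at Ptpmeg2 and mamo.

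Genes of several non-coding classes had TSS-proximal summits less often than the 13.1% of protein-coding genes. For pseudogenes the count was 8 of 330 (exact adjusted p = 5.62e-11), for microRNA genes 10 of 260 (adjusted p = 1.72e-06), for snoRNA genes 11 of 269 (adjusted p = 1.99e-06) and for other non-coding RNA genes 255 of 3029 (adjusted p = 6.13e-13). The odds ratio for snoRNA genes was 0.282, rose to 0.760 within 1000 bp, where the call ended (exact adjusted p = 0.229), and was 0.109 within 200 bp. The odds ratio for microRNA genes was 0.265, and 0.414 within 1000 bp. For other non-coding RNA genes it was 0.608, and 0.374 within 200 bp. Genes for tRNA stood at 30 of 290, an odds ratio of 0.763 (exact adjusted p = 0.224), and snRNA genes at 3 of 32, an odds ratio of 0.684 (adjusted p = 0.792). The snRNA ratio was 1.06 without replicate 1, 0.348 without replicate 2 and 0.322 without replicate 3, none past the threshold. The tRNA odds ratio also moved when a replicate was left out, to 0.506 without replicate 3 (exact adjusted p = 0.0112) and 1.01 without replicate 1. The tRNA genes also passed the threshold within 200 bp, at 0.602 (exact adjusted p = 0.0489). These p-values are from two-sided Fisher's exact tests, which were not matched on TSS number or gene length. Of the bound genes, 10 of 11 snoRNA and 104 of 255 other non-coding RNA genes stood within 1000 bp of a protein-coding TSS. The same held for 3 of 10 microRNA genes and 4 of 8 pseudogenes.

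Chromosome 4 carried 14 peaks, or 0.284%, against 0.971% of the assembled length, a ratio of 0.292 (adjusted p = 5.53e-08, exact binomial test). Its strongest peak lay 11 bp from the TSS of RpS3A, a ribosomal protein gene, at 67159 to 67303, with a relative signal of 1.32 ± 0.521 (SD, n = 3), and others lay in or near genes that included dati, Sox102F, zfh2, Mitf, pan and ci. The difference was not past the threshold when TSS-proximal peaks were compared with the share of protein-coding genes on this chromosome (ratio 0.751, exact adjusted p = 0.627). The pooled candidates had a similar share, 0.297%. The single replicates' strongest candidates gave 0.392% ± 0.204 (SD, n = 3). The X chromosome carried 18.8% of the peaks against 17.1% of the length, a ratio of 1.10 (exact adjusted p = 0.00386), and 18.4% ± 0.175 in the single replicates (SD, n = 3), but against its 17.9% of the pooled candidates the call ended (adjusted p = 0.344). Of the TSS-proximal peaks 19.4% lay on X, a ratio of 1.23 to its share of protein-coding genes (exact adjusted p = 0.000155). Arm 3L carried 22.7% against 20.4% of the length (exact adjusted p = 0.000153), but it held a similar 22.2% of the pooled candidates. No list held a region on the Y chromosome, which makes up 2.49% of the length and is rich in repeats.

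Summits were richer than their flanks in GAGA repeats and in runs of A. The sequence GAGAGAG, the element of the GAGA factor, occurred within 100 bp of 10.4% of the summits and in 3.87% of windows 1000 bp to one side, a ratio of 2.70 (adjusted p = 3.86e-37, exact McNemar test). In the single replicates this ratio was 2.56 ± 0.294 (SD, n = 3). At TSS-proximal summits the share was 15%, and at the others 7.68%. Against shuffled copies of the summit windows, chosen after seeing the data, the ratio was 5.05, but shuffling also breaks up repeats. Runs of A occurred at 20.6% against 12.8% (exact adjusted p = 3.25e-24), the TCT initiator of ribosomal protein genes at 29.2% against 22.4% (adjusted p = 9.35e-14) and the TATA box at 12.3% against 8.63% (adjusted p = 3.72e-08). The last 2 were not particular to promoters, since the ratios were 1.26 and 1.34 at TSS-proximal summits and 1.33 and 1.48 at the others. These 4 of the 31 motifs tested kept their call under all 10 alternatives. Of the others that were higher, CA repeats (ratio 1.52) lost the call in 3 of 10 alternatives, the Foxo element (ratio 1.31) in 3, the initiator (ratio 1.17) in 4 and core promoter motif 6 (ratio 3.17) in 7 of 9. Some of these calls ended when a replicate was left out, which also left fewer peaks. A call lost there need not come from that replicate. The Foxo ratio was 1.15 without replicate 1 and 1.17 without replicate 2 (exact adjusted p = 0.128 and 0.0688). The initiator ratio was 1.11 without replicate 3 (exact adjusted p = 0.103). For motif 6 the ratio was 3.75 without replicate 1 and 3.2 without replicate 2 (exact adjusted p = 0.0596 and 0.0687). The ratio of CA repeats ranged from 1.07 against pooled candidates outside the IDR peaks (exact adjusted p = 0.244) to 8.39 against shuffled windows. Lower at summits were the Pho element, at 6.69% against 8.98% (exact adjusted p = 0.000117), AGGTCA of nuclear receptors, at 3.40% against 4.97% (adjusted p = 0.000506), and the Ftz-f1 element, at 0.304% against 0.872% (adjusted p = 0.000952). The Pho call ended against shuffled windows (ratio 0.962, exact adjusted p = 0.702), the AGGTCA call in 2 of 10 alternatives and the Ftz-f1 call in 2, of which 1 was without replicate 1 (ratio 0.462, adjusted p = 0.0800). The STAT, Scalloped and homeodomain elements were lower, with exact adjusted p = 0.0199, 0.0274 and 0.0295, but lost the call or changed direction in 6, 9 and 10 of 10 alternatives. The Scalloped and homeodomain calls ended without any 1 of the replicates, at ratios of 0.877 to 0.898 and 0.869 to 0.965. Of 2080 words of 6 bases, 302 were more frequent and 558 less frequent at summits. By p, the words led with AGAGAG, at 19.4% against 9.20%, and its shifted form GAGAGA, followed by AAAAAA, at 47.6% against 34.3%, AAAATA, and ACACTG, at 14.3% against 6.79%. The GC content was 39.7% at summits and 41.7% in flanks.

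**Figure D4:**
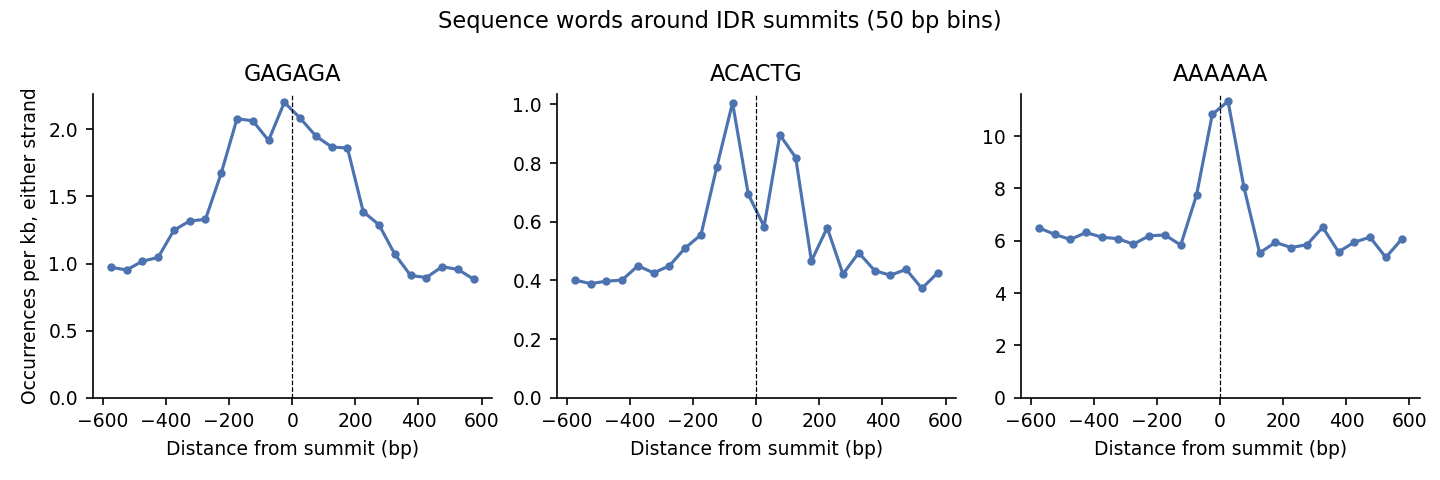
Sequence words around IDR summits. Lines give the occurrences per kb on either strand, on the y axis, in bins of 50 bp by distance from the summit on the x axis, for GAGAGA, ACACTG and AAAAAA. In windows 100 bp to each side, ACACTG occurs at 14.3% of the summits and in 6.79% of the flanks.

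The share of TSS-proximal peaks hardly followed signal, except among the strongest peaks. In 10 bins of signal it was 46.0% in the highest and between 35.5% and 39.4% in the others. It was 40.9% in the fifth of the peaks with the highest signal and 37.4% in the fifth with the lowest. Across peaks, the Spearman correlation between signal and TSS proximity was 0.0271 (p = 0.0565, permutation test). Ranked by the signal of replicate 2 or 3 it was 0.0483 (permutation p = 0.00074) and 0.0588 (p = 4e-05), past the threshold but small. Ranked by the signal of replicate 1 it did not pass the threshold.

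The same libraries called on the older dm3 build gave 4309 IDR peaks, of a median width of 430 bp, against 4934 on dm6. The share of strongest candidates that recurred between replicates was 69.8% on dm3 and 69.9% on dm6. Positions were not converted between the builds.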

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

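The matched gene sets, shuffled windows, other backgrounds for arms, alternatives for biotypes and leaving out replicates for motifs, arms and peak number were chosen after seeing the data. Of 707 values recomputed under an alternative, those for summary results kept their direction and side of the threshold, or stayed close, in 94 instances, moved in 7, gained the threshold in 2 and lost it in 3. For single lists, biotypes and motifs the counts were 508 kept, 57 lost, 28 gained and 8 reversed. A change of direction was counted as reversed only where a value passed the threshold. Where neither value passed it was counted as kept, such as the Rab list from an odds ratio of 1.24 to 0.449 in the peaks above the median signal. The gains were in the wnt, Hippo, proteasome, male germline and neuronal lists, tRNA genes, and the CACGTG, DRE, M1BP, Zelda, CTCF, GATA and Dorsal motifs. The promoter share stayed above background under every alternative run. Requiring a peak in the other replicates left 3269 to 3323 IDR peaks, fewer by construction. Against the pooled candidates, the X share of 18.8% and the chromosome 4 share of 0.284% lost the threshold, and so did 0.430% of TSS-proximal peaks on chromosome 4 against its genes. Matching on TSS number and gene length left 4 lists higher. With TSS-distal peaks alone, fewer peaks, 5 motifs were higher. There the M1BP motif reversed from a ratio of 1.54 to 0, lower past the threshold (exact adjusted p = 0.0269, McNemar test). Windows of 50 bp to each side left 3 motifs lower and leaving out a replicate 3 to 5, and TSS-proximal peaks alone gave 354 lower words of 6 bases, from fewer peaks. The trend with signal passed the threshold by the rank of replicate 2 (0.0483) and replicate 3 (0.0588) but not of replicate 1. The highest of 10 bins held 46.0% TSS-proximal peaks, against 35.5% to 39.4% in the others. The direction reversed for histone genes with clusters counted once (odds ratio 1.31), because their repeats then count as 1 cluster. It reversed for the CAGCTG E-box (1.90) and CTCF (1.34) against shuffled windows, for GATA (1.08), homeodomain (1.09) and STAT (1.12) against pooled candidates, and for homeodomain with flanks at 2000 bp (1.00). Except where stated, the cause was not tested. Including sequences beyond the major arms moved nothing, since no dm6 region lay there. Unknown depth limits what can be said of the weaker peaks.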

Other observations

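Except for the following, the tests in this part were chosen only after the result was seen. The tests of base composition and TSS location for CACTGAGA were written before their results, but the word had been picked from these same peaks. The comparison of TSS-proximal peaks on chromosome 4 with its share of genes was fixed before the data were examined. For GAGAGAG at TSS-distal summits the ratio had been fixed before the data were examined, but its use as a test was not. In 32 genes 10 or more summits lay within the gene, against a mean of 10.9 and at most 19 such genes in 200 random relocations. Counts in single genes depend on length, and relocation placed up to 92 summits in 1 gene. The highest observed counts were in sbb, a transcriptional corepressor gene, with 25 summits in 79099 bp, or 0.316 per kb against 0.0360 per kb over the genome, and in Tet, with 21 in 92952 bp. Svil and shn, which encodes a zinc finger factor of Dpp signalling, had 18 each, and CG1677 and the ecdysone-induced receptor gene Eip75B had 17 each. In kirre, 16 summits lay in 394149 bp, or 0.0406 per kb, close to the genome's density. Also in this group were Raf and mam with 15, psq with 15, E2f1 with 14, and EcR, the ecdysone receptor gene, with 10. Of 91 families grouped by symbol, chosen after seeing the data, 7 differed from other genes past the threshold. They were RpL and RpS, bound more often, and His, Cpr, Or, Gr and Ir, bound less often. The first 4 overlap lists described in the results, and odorant receptor genes (Or) stood at 0 of 59, gustatory receptor genes (Gr) at 0 of 60 and ionotropic receptor genes (Ir) at 0 of 60, with adjusted p = 0.00476 for each (Fisher's exact test). Families were compared with all other genes, without matching on TSS number or gene length and without counting clusters once. These p-values may therefore overstate the difference. Of the 9 bound mitochondrial ribosomal protein genes, 7 had the TSS of another gene closer to the summit, such as CenG1A for mRpS23 and Art3 for mRpS10.

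Cytosolic ribosomal protein promoters were bound far more often than other genes, at 57 of 92. The tables argue against the number of TSSs and gene length as the whole cause, since the count was 4.94 times that of matched random genes. They also argue against recovery of every housekeeping promoter, since 6.16% of 211 mitochondrial ribosomal protein, oxidative phosphorylation and proteasome genes were bound (exact 95% interval 3.32% to 10.3%). These 211 genes include variants such as COX4L and Prosalpha3T, so not all of them need be housekeeping genes. The mitochondrial ribosomal protein genes alone stood at an odds ratio of 2.48 against matched genes (adjusted permutation p = 0.102). Peaks of neighbouring genes are argued against as well, since the own TSS was nearest to the summit in 96.5% of the 57 bound genes. Non-specific recovery at highly transcribed promoters may still account for it, because no library without the tagged protein was analysed here, what the shared control alignment was made from is not given in the sources used here, and the share ranged from 77.2% to 39.1% between replicates. No biological explanation was tested.

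The words GAGAGAG and CACTGAGA were more frequent at summits than in flanks; CACTGAGA, seen in a scan of words of 8 and 10 bases in windows of 301 bp where it ranked 2, ranked 1 of 32896 words of 8 bases in windows of 201 bp and occurred at 167 summits (3.38%) and in 25 flank windows (0.507%), and in 3.09% ± 0.135 against 0.507% ± 0.0702 in the single replicates (SD, n = 3). For GAGAGAG, the location of TSSs is argued against as the whole cause, since its ratio was 2.02 at TSS-distal summits. Its ratio of 5.05 against shuffled windows cannot decide on base composition, because shuffling breaks up repeats. The flanks, at 3.87%, also held GAGAGAG more often than the shuffled windows, at 2.07%. For CACTGAGA the ratios were 10.4 against shuffled windows and 7.94 at TSS-distal summits. However, the word was picked for its frequency at these same summits against the same flanks. Its ratios were in part set by that choice, so no conclusion on base composition or the location of TSSs is drawn for this word. A test of masked repeats on the 211 window pairs without a masked base gave a ratio of 10 for GAGAGAG (p = 0.000121, exact McNemar test) but only 3 windows against 0 for CACTGAGA (p = 0.25, exact McNemar test), too few to decide, and was replaced after its result was seen by counting words without a masked base, where the ratios were 2.35 and 3.29. Copies of a dispersed repeat may still contribute, since 111 of the 167 CACTGAGA summits had only copies with a masked base, against 8 flank windows. That ratio of 13.9 was higher than the 3.29 for copies without a masked base. The copies also shared bases next to the word, with A in 84.7%, 85.2% and 81.3% of 176 copies at 2, 3 and 4 bases after it. At 2 bases before it, T stood in 53.4%. However, no base exceeded 42.6% at 15 to 30 bases from it, a distance chosen after bases nearer the word were seen. CACTGAGA was found and tested on the same peaks, so a sequence that recruits the protein or its partners is a hypothesis only, and no biological explanation was tested.

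Chromosome 4 held 0.292 times the peaks that its length would give. Masked repeats are argued against as the whole cause, since the ratio to its share of unmasked length was 0.321 (exact 95% interval 0.176 to 0.539). The IDR threshold is argued against as the whole cause as well, since the pooled candidates gave 0.305 (0.245 to 0.376), although the candidates of replicates 1, 2 and 3 varied widely, with 0.703%, 0.467% and 0.247% on this chromosome against 0.971% of the length, and so is the small number of protein-coding TSSs, since TSS-distal peaks gave 0.201 (0.0738 to 0.437). How well reads could be placed on this chromosome was not tested and may account for the deficit in part, and the TSS-proximal peaks did not differ past the threshold from its share of genes. No biological explanation was tested.

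The 167 peaks with CACTGAGA lay near a TSS less often than the others, at 19.2% against 38.3% (p = 2.17e-07, Fisher's exact test). The word occurred at 3.8% of summits on arms 2L, 2R and 3L, where it ranked 1, and at 2.79% on 3R, 4 and X, where it ranked 16. The 33 genes with a TSS-proximal summit and the word included NK7.1, Wdr37, numb, Duox and bib. A comparison of 32 gene lists with the other bound genes gave adjusted p = 1 for each (Fisher's exact test), but no list held more than 1 of the 33 genes, so it could hardly have found a difference.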
